A study of Mus musculus with 2 samples.

How the data were processed

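The series holds microRNA sequencing of total RNA from the left cerebral cortex of 2 male B6CASTF1/J mice on postnatal day 10, in 1 group of 2 biological replicates. Per the labels, the replicates come from tissue specimens numbered as separate males under 1 strain-level donor entry, and each has 1 library with inserts in a size range below 30. The group and replicate numbers follow the labels.

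The authors deposited raw read counts per miRNA gene for each library, against assembly mm10 and GENCODE annotation M21 per the text deposited with each sample. The aligner, the counting program and the trimming are not given in the sources used here. Each deposited file has 3 columns of counts. Their values show reads counted without regard to strand, on the strand of the gene, and on the opposite strand. The sense column was used, because it had the larger total of the 2 stranded columns. Where 2 miRNA genes overlap on opposite strands, the unstranded column gives few or none of their reads to either.

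The 4 rows of each file that name no gene were left out of library sizes and tests. Unmapped reads were 25.5% of all reads in replicate 1 and 42.4% in replicate 2, reads mapped to more than 1 place 38.2% and 28.3%, and mapped reads outside the listed genes 6.93% and 5.74%. Reads mapped to more than 1 place are counted for no gene, so hairpins with a near-identical copy are undercounted. A value per hairpin sums both arms, and arms were not analysed. No account was taken of CAST alleles that differ from mm10.

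The counts were divided by the sum of the sense column over the 2202 miRNA genes (2677910 and 1750076 reads) and given as CPM. Gene symbols, coordinates, strands and host genes came from the M21 annotation, which matched all 2202 identifiers. A gene was called detected at 2 CPM or more in both libraries, which equals 5.36 reads in replicate 1 and 3.50 in replicate 2. Hairpins were compared by their 20-base stretches to mark shared sequence, and hairpins that overlap each other on the 2 strands were not counted as sharing. The level that 3 reads give was 1.12 and 1.71 CPM. Intervals and such levels cover counting error only, since reads amplified by PCR are not independent molecules.

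With 1 group there was no comparison of conditions. The spread between the libraries was estimated with edgeR 4.0.16 (estimateDisp, intercept only, TMM) in R 4.3.3, with 100 bootstrap resamples of genes for its interval. Each gene at 2 CPM or more in either library was tested with Fisher's exact test against the remaining reads, two-sided, with Benjamini-Hochberg adjustment. The threshold was an adjusted p under 0.05 and a log2 ratio of 1 or more in size. Log2 ratios are replicate 2 over replicate 1 with 0.5 reads added to each count, and their counting intervals are exact binomial. List medians were placed among 10000 random lists of the same size, drawn from the 20 genes nearest each member in mean CPM. Only lists with 3 or more detected members were placed. Clusters were tested with 100000 permutations, and with 10000 where 1 cluster or family was left out. The p-values measure spread between these 2 libraries or among genes and say nothing of other animals. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the rest.

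The 16 lists, the 26 clusters, the tests of the libraries, lists and clusters, the alternatives (except the 1 named below) and the rule for named genes were fixed before the data were examined. The tests of explanations reported with the other observations were chosen after the results they bear on had been seen. An adjustment for hairpin GC content planned earlier fitted 0.200% of the variance of log2 ratios and moved no gene across the threshold, so it decided nothing. Named were the 15 genes with the highest mean CPM, up to 4 members of each list with the highest mean among those detected, the 5 largest log2 ratios per direction among genes past the threshold with a mean of at least 10 CPM, and members of a fixed cluster where its spread is described. Other names are marked as chosen after their values were seen. A list for choroid plexus and ependyma was written after the largest ratios had been seen.

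The steps were tested on simulated data. For the difference between the 2 libraries, with 525 genes tested and changed genes drawn below 1000 CPM, 88% of genes raised 3-fold, 66% of those lowered to 0.3333 and 2.0% of those raised 1.2-fold were called, and 0.31% of unchanged genes. These draws held counting error only, less than the spread between the real libraries. The 0.31% is therefore not the rate of false calls in the real libraries. The cluster test called 28 of 500 runs without and 500 of 500 with a shared effect over 50 genes. The list percentile left the range in 36 of 500 runs without a shift, more often than its nominal rate, and in 500 of 500 with one, over 400 genes. For the spread between the 2 libraries, simulated dispersions of 0.01, 0.1 and 0.3 were estimated as 0.0101, 0.102 and 0.276 over 451, 444 and 420 genes.

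Alternatives covered the CPM minimum, TMM or DESeq2 1.42.0 size factors in place of library totals or TMM, the unstranded column, the exclusion of genes with a copy number in their name, reads mapped to more than 1 place added to the total, each replicate left out and the Dlk1-Dio3 list added as a cluster. Leaving out each cluster in turn was added after the data were seen. Mature arms, length variants and alleles were not analysed here.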

Results

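The left cerebral cortex of male mice was profiled by microRNA sequencing on postnatal day 10. The animals were B6CASTF1/J, a hybrid of the B6 and CAST inbred strains, and the labels give 1 group of 2 biological replicates, numbered as separate males. No other tissue, age, sex or treatment was measured, so the text describes which microRNA (miRNA) genes were abundant, how much of the library each group of them took, and how far the 2 libraries differed. Reads were counted per miRNA gene, that is per hairpin precursor, and not per mature strand. Replicate 1 held 9089257 reads, of which 2677910 (29.5%) were assigned to a miRNA gene on its own strand. Replicate 2 held 7432614 reads, of which 1750076 (23.5%) were assigned. A count of 3 reads corresponded to 1.12 CPM in replicate 1, where CPM are assigned reads scaled to the same library total, and 1.71 CPM in replicate 2. Of 2202 listed miRNA genes, 442 (20.1%) reached 2 CPM in both libraries and are called detected, and 1458 had no read in either.

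Among reads assigned to 1 gene, which leave out those mapped to more than 1 place (51.2% and 49.2% of mapped reads in replicates 1 and 2), the most abundant were the let-7 family, miR-139 and miRNAs of the imprinted Dlk1-Dio3 region. Mirlet7i, a member of the let-7 family that accumulates as cells differentiate, was the most abundant at 81898 ± 752 CPM (SD, n = 2). It was followed by Mirlet7b at 75881 ± 308 CPM, Mir139 at 67357 ± 5152 CPM and Mirlet7g at 64893 ± 4752 CPM. Mirlet7i lies on chromosome 10 at 122985640 to 122985724 (mm10, minus strand), in an exon of the transcribed pseudogene D630033A02Rik. Mir139 lies on chromosome 7 at 101475376 to 101475443, in an intron of Pde2a. Mirlet7g lies on chromosome 9 at 106178840 to 106178927, in an intron of Wdr82.

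Among the next most abundant genes, Mir744, in an intron of Map2k4, reached 32203 ± 1525 CPM and Mirlet7d 28929 ± 290.3 CPM. Mirlet7e, Mir99a and Mir652 reached 24995 ± 670.4, 17477 ± 3241 and 16386 ± 41.1 CPM. Mir298, on chromosome 2 at 174267504 to 174267585, averaged 16911 CPM, but its SD was 14896 CPM, since replicate 2 held 4.30 times the CPM of replicate 1. The 10 most abundant genes took 47.3% of assigned reads in replicate 1 and 50.3% in replicate 2, a mean of 48.8% ± 2.15 (SD, n = 2). In replicate 1, 12 genes held 50% of the reads and 73 genes held 90%, against 10 and 75 genes in replicate 2. The share of the 10 most abundant genes fell to 21.7% when reads mapped to more than 1 place were added to the total, because those reads belong to no gene in the counts.

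**Figure D1:**
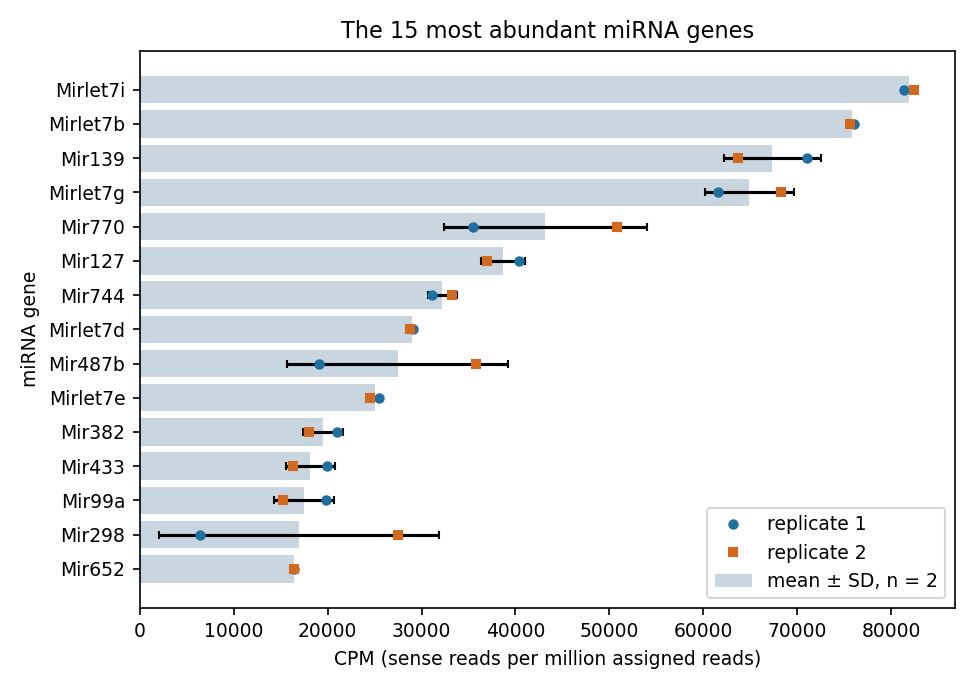
Horizontal bars give the mean CPM of the 15 most abundant miRNA genes with the SD of 2 libraries as error bars, and points give each library. The bars fall from 81898 CPM for Mirlet7i to 16386 CPM for Mir652, and Mir298 has the points farthest apart relative to its mean.

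The let-7 family as a whole, with 12 of 12 listed genes detected, held 28.6% ± 0.452 of assigned reads (SD, n = 2). Of the 12 genes, 6 share 20 bases with another hairpin, so the share leaves out reads that map to more than 1 copy. None of its members passed the library test described further on, with p adjusted over all genes or adjusted over the list alone. The Dlk1-Dio3 region of chromosome 12, from which miRNAs are transcribed on the maternal chromosome, held 22.3% ± 0.679. Of 58 listed miRNA genes on the plus strand between 109563692 and 109747960, 52 were detected and 25 averaged over 1000 CPM. Mir770, in an exon of the long noncoding RNA Meg3, averaged 43158 ± 10816 CPM and Mir127 averaged 38663 ± 2376 CPM. Mir487b averaged 27442 ± 11807 CPM, Mir382, in an exon of Mirg, 19521 ± 2140 CPM and Mir433 18165 ± 2563 CPM. Between the libraries, 49 of the 52 detected members stayed within 2-fold. The other 3 passed the library test, also when adjusted over the list alone, and all 3 were lower in replicate 2. They were Mir370, with a log2 ratio of -1.19, Mir539 with -1.56 and Mir544 with -1.21, named after their values were seen.

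**Figure D2:**
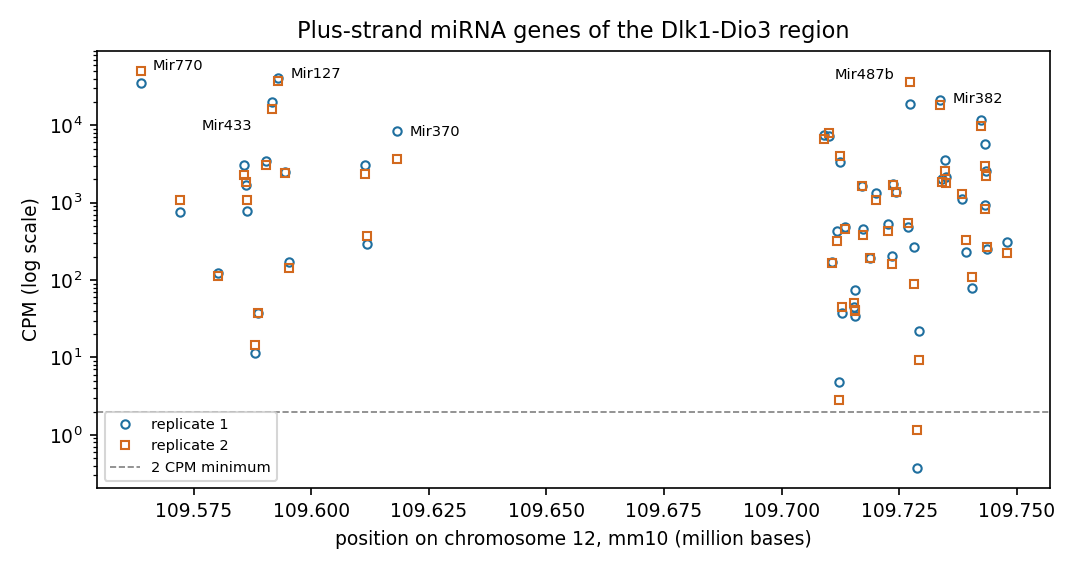
Points give the CPM (log axis) of each plus-strand miRNA gene of the Dlk1-Dio3 region with at least 1 read against its start on chromosome 12 of mm10, with circles for replicate 1, squares for replicate 2 and a dashed line at 2 CPM. Of 58 listed genes, 52 lie above the line in both libraries, and Mir770 and Mir127 have the highest means.

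Brain cell types were represented by lists fixed before the data were examined. The neuron-associated list (16 of 20 genes detected) held 4.35% ± 0.744 of assigned reads (SD, n = 2), or 2.02% when genes with a copy number in their name were left out. It was led by Mir128-1 at 13876 ± 6174 CPM, Mir137 at 9938 ± 2644 CPM, Mir132 at 6554 ± 3773 CPM and Mir128-2 at 4461 ± 1652 CPM. The endothelial and mural list held 1.44% ± 0.111 (0.433% with the unstranded counts), with the endothelial Mir126a, on chromosome 2 in an exon of Egfl7, at 10380 ± 1071 CPM, and the smooth muscle and pericyte genes Mir143 at 3847 ± 36.2 CPM and Mir145a at 199.7 ± 6.81 CPM. The microglia and leukocyte list held 0.790% ± 0.134, with Mir342 at 6206 ± 1305 CPM, Mir146 at 775 ± 140.0 CPM, Mir150 at 736 ± 153 CPM and Mir142, a marker of blood-derived cells, at 85.6 ± 7.86 CPM. The oligodendrocyte-associated list held 0.647% ± 0.145, with Mir23a at 5338 ± 1870 CPM, Mir338 at 621 ± 205 CPM, Mir219a-2 at 488 ± 214 CPM and Mir219a-1 at 19.0 ± 2.67 CPM. The astroglia-associated list held 0.841% ± 0.502, most of it from Mir99b at 7042 ± 5316 CPM, while Mir29a, Mir29c and Mir29b-2 reached 1078 ± 241, 197 ± 42.4 and 41.8 ± 5.81 CPM. Members that share 20 bases with another hairpin numbered 14 of 20 in the neuron-associated list and 4 of 5 in the oligodendrocyte-associated list. They numbered 3 of 6 in the astroglia-associated, 1 of 6 in the microglia and leukocyte, and 0 of 3 in the endothelial and mural list. Reads that map to more than 1 copy are left out, so the shares cannot be compared between lists. miRNAs are shared between cell types, so these lists are associations and not pure markers.

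The proliferation clusters list, which holds the Mir17 and Mir106b clusters, took 1.02% ± 0.0399 of assigned reads, with Mir93 at 3794 ± 118 CPM, Mir17 at 3259 ± 504 CPM, Mir106b at 1027 ± 84.1 CPM and Mir92-1 at 854 ± 263 CPM. The activity-regulated list, whose members Mir132 and Mir212 are induced by neuronal activity, took 0.869% ± 0.368. Most of it came from Mir132 at 0.655% ± 0.377, with Mir134 at 1939 ± 104 CPM and Mir212 at 197 ± 14.9 CPM. All 3 genes are also in the neuron-associated list, so results of these lists are not separate. The Sfmbt2 multicopy list took 0.207% ± 0.0132, led by Mir467d at 851 ± 120 CPM, Mir669c at 539 ± 127 CPM, Mir467e at 336 ± 9.13 CPM and Mir669o at 198 ± 63.2 CPM. Of its 77 genes 75 share at least 20 bases with another hairpin, so the 8 detected ones are uncertain.

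The markers of tissues other than brain that could be counted were low. The liver, pancreas and gut list held 0.0250% ± 0.00485 of assigned reads (SD, n = 2), led by Mir375 at 128 ± 15.5 CPM and Mir122 at 50.4 ± 7.42 CPM, with Mir194-2 at 27.9 ± 20.4 CPM and Mir217 at 26.0 ± 19.8 CPM. The epithelial miR-200 list held 0.00841% ± 0.000255, with Mir429 at 32.4 ± 0.990, Mir200c at 25.4 ± 6.89, Mir200b at 21.1 ± 11.3 and Mir200a at 2.83 ± 0.840 CPM. The striated muscle list held 0.00635% ± 0.000796, with Mir206 at 23.7 ± 2.87, Mir499 at 22.2 ± 0.179, Mir208a at 12.96 ± 6.72 and Mir208b at 4.70 ± 1.80 CPM, but 5 of its 9 genes, those of miR-1a and miR-133a among them, share 20 bases with another hairpin, so its share leaves out reads that map to both. The sensory miR-183 list held 0.00235% ± 0.000327, with Mir183 at 12.8 ± 1.25 and Mir182 at 10.3 ± 4.92 CPM. The pluripotency list held 0.000659% ± 0.000124, and Mir302d was its 1 detected member of 14 at 3.94 ± 2.34 CPM. The erythroid list differed between the libraries, at 0.0814% of reads in replicate 1 (95% Wilson interval 0.0781 to 0.0849) and 0.00566% in replicate 2 (0.00465 to 0.00689), a mean of 0.0436%. With the unstranded counts the mean was 0.00335%, since Mir451a, which overlaps Mir451b on the opposite strand, then had 0 reads.

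**Figure D3:**
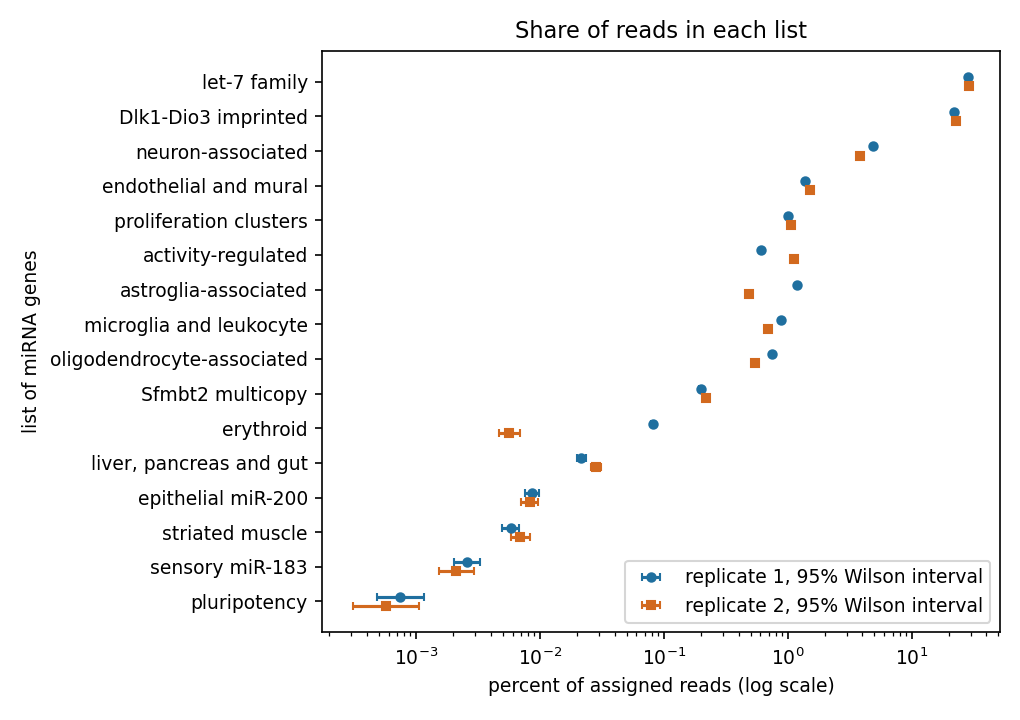
Points give the percent of assigned reads (log axis) in each of 16 lists, with circles for replicate 1, squares for replicate 2 and 95% Wilson intervals that cover counting error only. Shares run from 28.6% on average for the let-7 family to 0.000659% for the pluripotency list, and the erythroid list has the widest gap, 14.4-fold.

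Several miRNAs known to be abundant in brain had few assigned reads. Their genes exist in copies that share sequence, and reads mapped to more than 1 place are assigned to no gene. The 3 genes of miR-124, a neuronal miRNA, had 10 and 2 reads (Mir124a-1), 0 and 4 reads (Mir124a-2) and 7 and 2 reads (Mir124a-3) in replicates 1 and 2. Mir9-3 reached 118 ± 60.1 CPM and Mir9-1 34.6 ± 6.05 CPM (SD, n = 2). Mir26a-1 and Mir26a-2 reached 52.7 ± 53.9 and 38.5 ± 32.8 CPM. The muscle genes Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 had 0 reads in both libraries, under the 3-read level of 1.12 and 1.71 CPM, and they also share sequence with a copy. Of 1087 genes that share at least 20 bases with a hairpin at another locus 87 (8.004%) were detected, against 355 of 1115 (31.8%) that do not. The sharing genes include 75 of the 77 genes of the Sfmbt2 multicopy list and may also differ in expression. The contrast therefore does not show by itself that mapping lowered the counts. Apart from Mir26a-1, the genes of this paragraph were named after their values were seen, and their read counts are lower limits for the mature miRNA.

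Hairpins of 1 primary transcript had unequal counts. Of 26 fixed clusters with at least 2 detected members, 18 had members over 10-fold apart in mean CPM, and the median ratio of the highest to the lowest member was 13.3. In most of these 18 the lowest member shares 20 bases with another hairpin, so its reads may be undercounted and the ratio inflated. In some, such as those of Mir23b and Mir181b-2, the highest member shares 20 bases too, so the ratio could be off in either direction. Mir30d (12391 ± 627 CPM) stood 91.3-fold above Mir30b (136 ± 4.49 CPM), and neither shares 20 bases with another hairpin. Mir143 stood 19.3-fold above Mir145a, Mir93 33.2-fold above Mir25 (114 ± 3.86 CPM) and Mir132 20.9-fold above Mir212 in replicate 1 and 44.5-fold in replicate 2. Larger ratios involved members that share sequence with a copy elsewhere. Mir23b (10100 ± 3538 CPM) stood 409-fold above Mir24-1 (24.7 ± 0.986 CPM), Mir181b-2 (6797 ± 319 CPM) 393-fold above Mir181a-2 (17.3 ± 5.09 CPM) and Mirlet7d 190-fold above Mirlet7f-1 (152 ± 18.7 CPM).

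The 2 libraries ranked the miRNA genes alike, with differences at single genes. Across the 442 detected genes, Spearman's rho was 0.970 (bootstrap 95% interval over genes 0.960 to 0.977) and Pearson's r of log2(CPM + 1) was 0.978. Genes are not independent replicates, so these values carry no p. The median absolute log2 ratio was 0.35, a 1.27-fold difference, and 304 genes (68.8%) lay within 1.5-fold. The biological coefficient of variation estimated by edgeR was 35.5% (bootstrap interval over genes 29.5% to 40.9%). With 1 library per animal it mixes differences between animals with those of dissection and library preparation. The coefficient was 24.4% for genes at 2 to 10 CPM, 35.6% at 10 to 100 CPM, 44.6% at 100 to 1000 CPM and 27.5% above 1000 CPM. Only genes at 2 CPM or more in both libraries entered, which limits the spread that genes at 2 to 10 CPM can show. The libraries differed by far more than counting error (chi-square 124119 on 484 degrees of freedom), so they are not 1 library deposited again.

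The genes that differed most between the libraries included the red blood cell miRNAs Mir451a and Mir144, and Mir301, Mir153 and Mir344b, all lower in replicate 2. Mir31, Mir34c, Mir26a-1, Mir669e and Mir1298 were higher in replicate 2. Mir451a, on chromosome 11 at 78073170 to 78073241, had 1973 reads in replicate 1 and 36 in replicate 2, a log2 ratio of -5.14 (95% counting interval -5.68 to -4.69). Mir144, its neighbour at 78073005 to 78073070, had 140 and 18 reads (log2 ratio -2.31, -3.14 to -1.63). Mir301, in an intron of Ska2, had 3764 and 89 reads (-4.78, -5.11 to -4.49), and Mir153, in an intron of Ptprn2, had 1180 and 96 reads (-2.999, -3.32 to -2.70). Mir344b had 57 and 5 reads (-2.77, -4.57 to -1.59). Mir31, on chromosome 4 at 88910557 to 88910662, had 224 and 1887 reads (3.69, 3.49 to 3.89), and Mir34c, on chromosome 9 at 51103034 to 51103110, had 250 and 1738 reads (3.41, 3.22 to 3.61). Mir1298, in an intron of the serotonin receptor gene Htr2c, had 571 and 1702 reads (2.19, 2.05 to 2.33). Mir26a-1 and Mir669e, which each share 20 bases with another hairpin, had log2 ratios of 2.63 and 2.56.

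In all, 65 of 542 tested genes passed the library test, 31 higher and 34 lower in replicate 2. With TMM effective library totals 67 passed, of which 37 were higher, so which direction held more genes depended on the scaling. The test was Fisher's exact test (two-sided) on the reads of each gene, with Benjamini-Hochberg adjusted p under 0.05 and a log2 ratio of at least 1 in size. Without the minimum on the ratio the count was 229. The test compares these libraries and not conditions, and its intervals cover counting error only. In 20 simulated pairs with the spread edgeR estimated and no changed gene, the median count was 85 and every pair gave at least 65, where the spread came from these same libraries. In 100 simulated pairs with counting error only, the median count was 0 and the highest was 1.

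**Figure D4:**
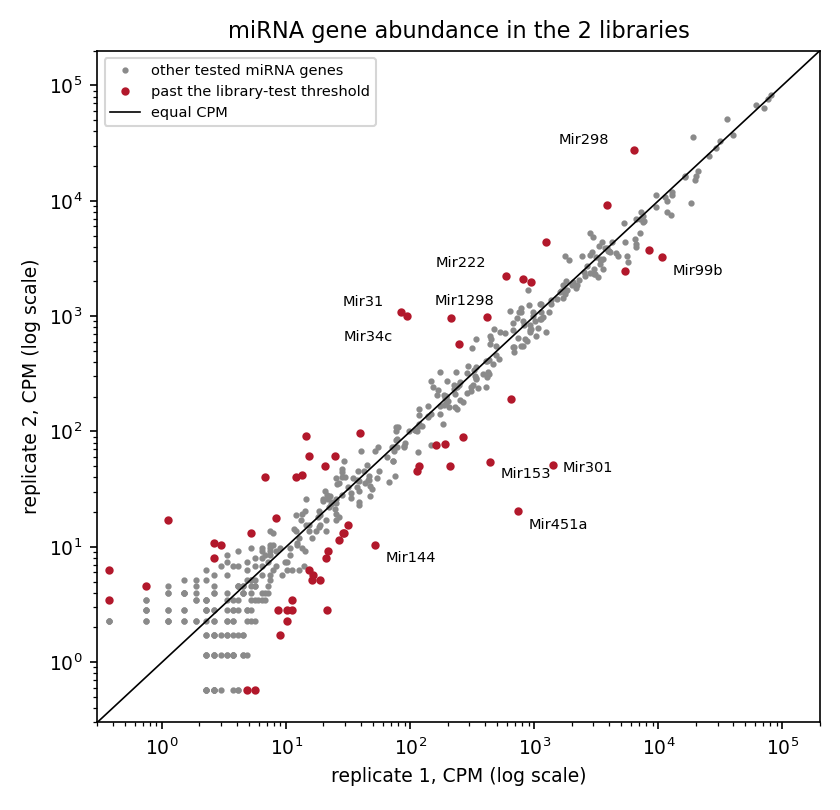
Each point is 1 miRNA gene at 2 CPM or more in either library, with its CPM in replicate 1 and replicate 2 on log axes; red marks the genes past the library-test threshold and the line marks equal CPM. Genes with 0 reads in 1 library, 18 of 542 tested and 4 of the 65, are not drawn; Mir451a and Mir301 lie farthest below the line among the named genes.

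By list, the erythroid genes had the lowest percentile, which rests on 1 locus. Of 3 members, Mir451a and Mir144, hairpins of that locus, were lower in replicate 2, also when adjusted over the list alone, and Mir486 had 68 and 45 reads (log2 ratio 0.02). The list's median log2 ratio of -2.31 lay below all 10000 random lists of the same size matched on mean CPM, which treat the 2 hairpins as independent. The neuron-associated list had a median of -0.30 (percentile 1.52), with 3 of 20 tested genes past the threshold, or 4 when adjusted over the list alone. Mir153 and Mir9-3 (log2 ratio -1.08) were lower and Mir132 (1.25) was higher in replicate 2, and the added gene was Mir124a-2 with 0 and 4 reads. With the unstranded counts its median was -0.15 (percentile 22.8). The astroglia-associated list had a median of 0.45 (percentile 97.9), opposite in sign to its share of reads, which was 1.196% in replicate 1 and 0.485% in replicate 2 because Mir99b, its only called member over all genes and over the list alone, had a log2 ratio of -1.72. That percentile was 95.5 with a 10 CPM minimum and 97.2 with the unstranded counts. These were 3 of 14 lists with a percentile outside the central 95% of random lists, and unchanged lists fell outside in 36 of 500 simulated runs. The simulated lists all had the same size and held independent genes, which does not hold for the real lists.

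The other 11 lists lay inside that range. The activity-regulated list had a median log2 ratio of 0.16 (percentile 93.5), Sfmbt2 multicopy 0.27 (90.1), let-7 0.00 (87.1), liver, pancreas and gut 0.25 (85.4), endothelial and mural 0.07 (84.6) and oligodendrocyte-associated 0.21 (78.0). The share of the oligodendrocyte-associated list went the other way, from 0.749% in replicate 1 to 0.544% in replicate 2, because Mir23a, which holds most of it, had a log2 ratio of -0.73, against 0.69 for Mir338 and 0.92 for Mir219a-2. Striated muscle had 0.14 (77.3), proliferation clusters 0.01 (69.1), epithelial miR-200 0.08 (62.0), microglia and leukocyte -0.23 (26.7) and Dlk1-Dio3 -0.12 (17.2). With a 10 CPM minimum the liver, pancreas and gut list had a median of 0.95, above all random lists. Among these lists the counts past the threshold, adjusted over all genes and adjusted over the list alone, were 2 and 3 for Sfmbt2 multicopy (Mir669e and Mir669l, with Mir297a-2 added). They were 2 and 2 for liver, pancreas and gut (Mir194-2 and Mir217) and 3 and 3 for Dlk1-Dio3. They were 1 and 1 for activity-regulated (Mir132), striated muscle (Mir208a), proliferation clusters (Mir363) and epithelial miR-200 (Mir200b), and 0 and 0 for the rest. Mir669l and Mir297a-2 were named after their values were seen. The pluripotency and sensory lists had under 3 detected members, and none passed.

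Hairpins of 1 cluster deviated together between the libraries, but this rested on 1 cluster. Over 62 genes in 26 clusters the variance of cluster mean log2 ratios was 0.702, against a median of 0.388 when genes were reassigned (one-sided permutation test, 100000 permutations, p = 0.00437). Without the pair of Mir144 and Mir451a the variance was 0.189 and the permutation p was 0.386 (10000 permutations), an alternative chosen after seeing the data. Mir221 and Mir222 were both higher in replicate 2 in ratio, at 0.89 and 1.91. Members of other clusters parted. Mir16-1 (-1.75) and Mir16-2 (-1.23) were lower in replicate 2, while their cluster partners Mir15a (0.47) and Mir15b (0.81) had ratios above 0. Mir99b (-1.72) shares a transcript with Mirlet7e (-0.05) and Mir125a (-0.18).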

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

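Reads outside the sense counts were looked at in both libraries, since no control sample gives a background. Opposite-strand reads at miRNA genes with no miRNA gene on the other strand numbered 101 over 26 genes in replicate 1 and 61 over 16 genes in replicate 2. Sense reads made up 99.996% of the reads of both strands at such genes in each library. Reads mapped to more than 1 place made up 51.2% of mapped reads in replicate 1 and 49.2% in replicate 2, or 1.29 and 1.202 for every assigned read. Reads mapped outside the listed miRNA genes made up 6.93% and 5.74% of all reads. The genes behind the last 2 kinds of read were not analysed here.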

How the results depend on the processing

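The log2 ratios of the 10 genes named for the largest differences kept their direction and stayed past the threshold under TMM and, where reads were left, the unstranded column. Shares were compared with the SD of 2 libraries, which leaving out 1 of 2 replicates cannot exceed. Leaving out each cluster in turn was chosen after seeing the data, and all other alternatives were planned. No paired analysis was possible because the series has 1 group. With the unstranded column, the share of the 10 most abundant genes was 51.9%, and the endothelial and mural share 0.433%, because Mir126a overlaps a miRNA gene on the other strand. The erythroid share fell from 0.0436% to 0.00335% and Mir451a from 379 to 0 CPM for the same reason, within SDs that are wide because the libraries differ. The epithelial miR-200 share was then 0.00899%, proliferation clusters 1.10%, let-7 27.8% and Sfmbt2 multicopy 0.222%. The median log2 ratio was -0.15 for the neuron-associated and 0.44 for the astroglia-associated list, and the cluster variance was 0.222 (permutation p = 0.409). Of genes detected by sense counts 27 were lost, all with an opposite-strand miRNA gene. Without multi-copy genes the shares were 2.02% (neuron-associated), 0.00880% (epithelial miR-200), 0.980% (proliferation clusters), 29.2% (let-7) and 23.4% (Dlk1-Dio3). With a 10 CPM minimum the median was 0.44 for the astroglia-associated list and 0.95 for liver, pancreas and gut. With no minimum Spearman's rho was 0.954. Adding reads mapped to more than 1 place gave a share of 21.7% for the 10 most abundant genes, and dropping the ratio minimum gave 229 genes in the library test. The cluster variance fell to 0.189 without Mir144 and Mir451a, and the permutation p was at most 0.0133 when any other cluster was left out. TMM moved every log2 ratio by 0.08 and gave 67 genes in the library test, 61 of them among the 65 and 37 higher in replicate 2, against 31 of 65. The coefficient of variation lay between 34.9% and 36.6% under its alternatives. Detected genes numbered 487 without replicate 1 and 497 without replicate 2. Where no other value decides it, the cause was not tested. Depth limits genes near 2 CPM, which rest on 5.36 and 3.50 reads.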

Other observations

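The library test and the placing of the erythroid list among random lists were fixed before the data were examined, and the tests of GC content, shared transcription, families and the choroid plexus list, with the reading of the erythroid list as red cells, were chosen after the results they bear on had been seen, at least in part. Genes hosted by the serotonin receptor gene Htr2c on the X chromosome had ratios above 0 together, named after their values were seen. Mir1298 had 571 and 1702 reads in replicates 1 and 2, Mir448 66 and 108 (log2 ratio 1.32), Mir1264 75 and 82 (0.74), Mir764 53 and 44 (0.35) and Mir1912 0 and 8. Mir34b, the cluster partner of Mir34c, had 3 and 30 reads. Mir298 and Mir296, neighbours on chromosome 2, went opposite ways, with log2 ratios of 2.11 and -1.11.

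Mir451a and Mir144 were lower in replicate 2. The 20 detected genes nearest each in hairpin GC content did not, as a set, move with them. Their median log2 ratio was -0.00847 in the direction of the change (quartiles -0.43 and 0.39). The test was chosen after the planned GC adjustment had fitted almost no variance, so its outcome could be foreseen. It covers hairpins only, and the GC content of the shorter sequenced inserts was not tested, so it does not settle GC content as a cause. Red blood cells left in the replicate 1 tissue stay open, since 0 of 10000 matched random lists had as low a median, but Mir451a and Mir144 lie at 1 locus and prompted the idea. Mir486, the list's other member and abundant in red cells, stood at 25.4 and 25.7 CPM, but its hairpin shares 22 bases with Mir3107 on the opposite strand, so its mature reads could map to both. A difference between the animals stays open and was not tested.

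Of the genes tested, 65 passed the library test. The 20 detected genes nearest each in hairpin GC content did not, as a set, move with them. Their median log2 ratio was -0.0216 in the direction of the call (quartiles -0.39 and 0.29). Here too the earlier GC adjustment made the outcome foreseeable and the inserts were not tested, so GC content is not settled as a cause. Shared transcription is argued against as the whole cause at hairpins of the fixed clusters, since the 13 partners of 9 called genes there had a median log2 ratio of 0.0547 in the direction of the call (quartiles -0.47 and 0.26), with Mir144 and Mir451a, and Mir221 (0.89) beside Mir222, as exceptions. Among these pairs, those of Mir16-1 and Mir16-2 are limited by sequence shared with a copy. Those of Mir200a (6 and 6 reads) and Mir363 (41 and 11 reads) are limited by low counts. Mir34b with Mir34c and the genes hosted by Htr2c lie outside the fixed clusters and had ratios above 0 together. Sequence-dependent capture of the mature miRNA may contribute, since 89 genes in 37 name families at separate loci deviated together by family (permutation p = 0.00089, and at most 0.0103 without any 1 family). Mir16-1 with Mir16-2 and Mir301 with Mir301b (-1.80, named after its value was seen) were among them. Families without hairpins that share 20 bases, 32 genes in 14 families, also deviated together (permutation p = 0.00046). That test was not repeated with each family left out. In the families that do share sequence, such as Mir16-1 with Mir16-2, reads common to the copies are assigned to no gene. Their assigned reads thus need not be those of the shared mature miRNA. Shared regulation of a family would give the same result, and no test here parts it from capture.

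Mir34c, Mir449a, Mir448 and Mir1298, known from choroid plexus and ciliated ependyma, were higher in replicate 2. The 20 detected genes nearest each in hairpin GC content did not, as a set, move with them. Their median log2 ratio was -0.155 in the direction of the change (quartiles -0.39 and 0.15). For the reasons given above, this does not settle GC content as a cause. Choroid plexus or ependymal tissue in the replicate 2 sample stays open, since among the 8 list members not used to form the idea only Mir204 (log2 ratio 0.60) is both detected and away from the genes that prompted it. With no CPM minimum the 8 had a median of 0.671 (percentile 99.1 of matched random lists), a setting that replaced minima of 2 CPM in both libraries (3 members, 0.60, percentile 96.1) and in either (6 members, 2.24, percentile 100) after their values were seen, since the change decides which members pass those. Members among the 8 with few reads went different ways, named after their values were seen. Mir449b had 3 and 0 reads (log2 ratio -2.19), Mir211 3 and 2 (0.13) and Mir449c 0 and 6. The list's share of reads, 0.141% in replicate 1 and 0.388% in replicate 2, includes the genes that prompted it and supports nothing further, and a difference between the animals stays open.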
